A study of Rattus norvegicus with 12 samples.

How the data were processed

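Total RNA from the snap-frozen livers of 12 male rats, 6 PCK and 6 Sprague Dawley control animals of 10 weeks, was isolated with Trizol, turned into biotinylated cRNA and hybridised to Affymetrix arrays, per the labels' protocols. The rats ate a standard diet with 19% protein and drank tap water freely, also per the labels. Groups and replicate numbers were taken from the sample titles.

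The authors deposited 1 table of 19239 probe sets for the 12 arrays. Its values are log2 signals as far as the values show: they run from 5.14 to 13.98 with a median of 5.66 and none is negative. The sorted values of all 12 deposited columns are identical, so the arrays share 1 distribution, as quantile normalization of summarised probe sets gives; the summarisation method, its version and the array type are not given in the sources used here. A difference in total RNA content between livers would have been removed by this step, and a gene that is the brightest on every array, here Alb, is fixed by it. The columns hold no detection calls and no control probe sets, so signal near the bottom of the range could not be told from background. The lower quartile of the values was 5.36 and the upper quartile 6.98.

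Probe sets are gene-level, 1 for each gene. The platform's annotation gave 1 gene symbol for 16592 probe sets, several for 0 and none for 2647. Symbols were updated through the gene identifier in the RefSeq gene table of assembly GRCr8: 13101 were the same, 3326 were older symbols and were replaced, 26 differed and 139 were not in the table, and the platform's symbol was kept for the last 2 groups. The 2647 unnamed probe sets entered only 1 alternative.

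Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes at default settings, 2-sided) on the deposited log2 values, with Benjamini-Hochberg adjustment over 16592 genes and a threshold of 0.05. All genes were tested; no filter on signal was set. Fold changes are PCK minus control on the log2 scale, and SE is the moderated standard error. Gene lists with at least 5 measured members were tested with camera at a preset correlation of 0.01, adjusted over 35 lists, with an estimated correlation and fry as alternatives. Principal components used centred values of all genes. Exact permutation tests used every assignment of 12 arrays to 2 groups of 6. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

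The design, the lists, the alternatives and the rule for named genes were set before the data were examined. The rule named Pkhd1, the 10 largest rises and 10 largest falls among called genes whose groups did not overlap, and for each list up to 3 called members with the largest absolute log2 fold change. In a list with no called member up to 2 with the smallest p would have been named. Other genes in the text were chosen after their values were seen, as further members of a list or to give its exceptions. The 35 lists cover markers of cholangiocytes, hepatocytes, pericentral and periportal hepatocytes, stellate cells, macrophages, T and NK cells, B and plasma cells, neutrophils, endothelium, red blood cells, and pancreas, fat and muscle. They also cover extracellular matrix, cell cycle, cystic disease and cilium, YAP/TAZ targets, sphingolipids, glycerophospholipids, fatty acid and triglyceride synthesis, fatty acid oxidation and PPAR alpha targets, cholesterol synthesis, bile acids, and cytochrome P450 and other drug metabolism. The rest are male-biased and female-biased liver genes, glucose metabolism, acute phase and complement, cytokines and chemokines, interferon response, antigen presentation, circadian clock, immediate early genes, unfolded protein response, NRF2 targets, and oxidative phosphorylation. Some lists share members, such as Bicc1, Lpin1, Me1, Tat and Cyp3a18, and are not independent. Members that no named probe set covers, Fasn, Acta2 and Sox9 among them, were not analysed here.

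Alternatives varied the normalization, the filter on dim genes, the probe sets, the variance model, array weights, the replicate number as a block, the thresholds and the set test, and left out each array in turn. Alternatives added after the data were seen centred the arrays on the brightest 25% of genes and left out control 5, control 6 and PCK 6, which had the lowest scores of their groups on component 2 or 3. The fit and camera were tested on simulated data for this comparison, drawn for 16592 genes from their control means and residual SDs. Of 200 changed genes, 97% of those at 1.5-fold and all of those at 2-fold were recovered, and 14 of 211 calls (6.64%) were false. With no gene changed 0 genes were called. Of 35 simulated lists of 30 genes, the 2 shifted by 0.3 were called in the right direction and 0 of the others were. The simulated genes were drawn independently, while the correlation estimated from the arrays reached 0.586, for cholesterol synthesis. The simulation therefore does not show how often camera calls lists of correlated genes falsely. It also set no lower limit on the signal, so recovery of falls in dim genes may be overstated. No gene was changed by less than 1.5-fold, and no normalization step was simulated. In the data 6362 genes were called, 61.6% of them under 1.2-fold. Recovery and the share of false calls for so many small changes are therefore not known from it.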

Results

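RNA levels were compared by microarray between the cystic livers of 6 PCK rats and the livers of 6 Sprague Dawley control rats, all male and 10 weeks old. The PCK rat descends from a Sprague Dawley colony and carries a mutation in Pkhd1, the gene altered in human autosomal recessive polycystic kidney disease; it develops cysts in the kidneys and in the bile ducts of the liver. The series title concerns lipid markers of polycystic disease, and the arrays addressed which genes differed in the liver. Values were log2 signals of 16592 named genes on each of the 12 arrays, in an animal-by-animal table. The labels call the arrays biological replicates, and their number limits the precision of each value.

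PCK livers differed from control livers in many genes. Genes of bile duct epithelium, extracellular matrix, cell division, macrophages and fatty acid and cholesterol synthesis were higher in PCK livers. With a correlation estimated from the arrays the cell division list kept its call, and the adjusted p was 0.0893 for bile duct epithelium, 0.302 for matrix, 0.432 for macrophages, 0.0590 for fatty acid synthesis and 0.399 for cholesterol synthesis. Genes of fatty acid oxidation, bile acid synthesis, cytochrome P450 metabolism and male-biased liver expression were lower. Of these the male-biased list kept its call with an estimated correlation, and the adjusted p was 0.130 for fatty acid oxidation, 0.0781 for bile acids and 0.198 for cytochrome P450 metabolism. The largest differences exceeded 5 log2 units, as for Lcn2, an iron-siderophore binding protein of the acute phase, at 11.49 ± 0.41 (SD, n = 6) in PCK and 5.88 ± 0.40 (SD, n = 6) in control livers. With limma, 6362 of 16592 genes (38.3%) changed, 2882 higher and 3480 lower in PCK livers. Of these, 261 changed at least 2-fold, 168 higher and 93 lower, and 3920 (61.6%) changed by less than 1.2-fold. The split of the small changes depended on the centring: with the arrays centred on the brightest 25% of genes, a setting chosen after the data were seen, 63.2% of 6904 called genes were higher, against 45.3% of the 6362.

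Pkhd1 itself, which encodes the cilium and membrane protein fibrocystin, was higher in PCK livers, at 8.12 ± 0.36 against 7.07 ± 0.23 (log2, SD, n = 6 each). The difference was 1.05 ± 0.17 (log2, SE; limma adjusted p = 0.000462), and the PCK values, 7.65 to 8.75, lay above the control values, 6.60 to 7.21. It stayed between 0.92 and 1.14 when any 1 array was left out. Where the probes lie relative to the mutation is not known here, so the value does not check the genotype.

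The arrays fell into their labelled groups. The first principal component held 74.5% of the variance and gave PCK livers a mean score of 20.6 ± 2.59 and control livers -20.6 ± 1.43 (SD, n = 6 each; exact permutation test, 2-sided p = 0.00216, the smallest possible). The second held 5.42%, with control 5 lowest, at a score of -15.1, and no difference between the groups passed the test (exact permutation p = 0.983). Correlations between arrays ran from 0.994 to 0.997 within control, from 0.996 to 0.998 within PCK and from 0.975 to 0.985 between groups, over genes, which are not independent replicates. In 1827 genes all PCK values lay above all control values and in 1751 all lay below, together 21.6% of genes where chance gives 0.216%.

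**Figure D1:**
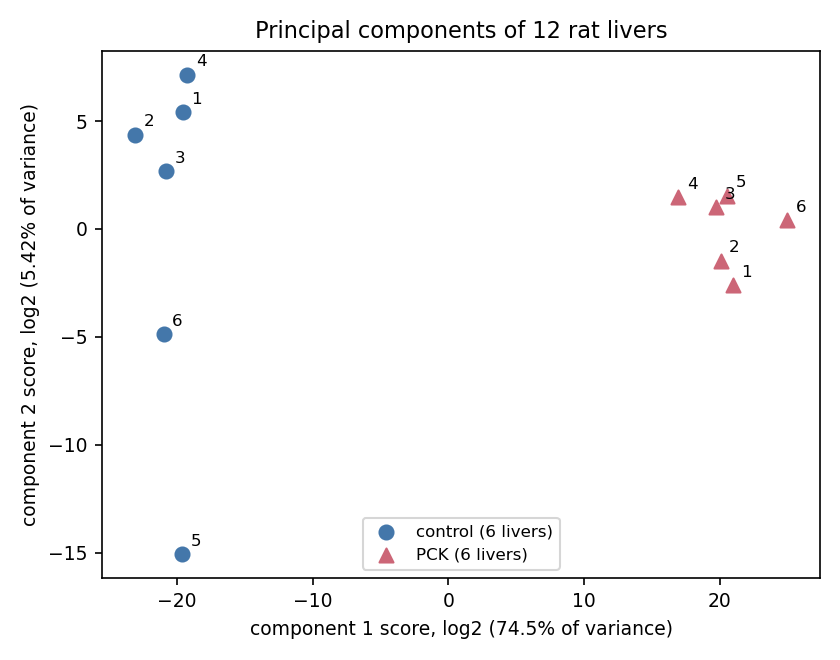
Scores of the 12 livers on the first (x axis) and second (y axis) principal components of the centred log2 values, with the replicate number beside each point. The 6 PCK livers lie between 16.96 and 24.98 on the first component and the 6 control livers between -23.1 and -19.2.

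The 10 largest rises were taken among genes whose groups did not overlap. Dmbt1, a secreted mucosal scavenger receptor, rose by 4.65 ± 0.14 (log2, SE; limma adjusted p = 4.67e-09), Reg3b, a secreted lectin, by 4.16, and Lcn2 by 5.61. Pnpla3, a lipid droplet enzyme of triglyceride and retinyl ester turnover, rose by 4.81 ± 0.22 (adjusted p = 7.81e-08). Abcb1b, a multidrug efflux pump, rose by 3.87, Enpp5 by 3.89, Casp12 by 4.13, Serpinb9b by 3.86 and Tsx by 4.99. Ugt2b, a glucuronosyltransferase, had the largest rise, 5.86 ± 1.09 (adjusted p = 0.00146), with an uneven control group: control 4 was at 12.65, near the PCK mean of 12.73 ± 0.051, and the other 5 control livers at 5.64 to 5.79. Without control 4 the rise was 7.01. Several of these genes were near the bottom of the signal range in control livers (Tsx 5.33, Reg3b 5.25, Abcb1b 5.59, Pnpla3 5.63, where the median of the table is 5.66). Their folds depend on a level that cannot be told from background without detection calls.

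The 10 largest falls among genes whose groups did not overlap ranged over several kinds of gene. Dhrs7l1, a short-chain dehydrogenase listed by the array as Dhrs7, fell, at -4.69 ± 0.20 (log2, SE; limma adjusted p = 5.95e-08). Cyp3a18 fell (-3.55) and Cyp3a9 (-2.87), both cytochrome P450 enzymes of a family whose near-identical members array probes may not separate. The sulfotransferase Sult2a1 fell (-2.93), the flavin monooxygenase Fmo1 (-2.76), the alcohol dehydrogenase Adh6 (-2.63), the transporter Ust5r (-2.60) and Sez6 (-2.73). Nox4, an oxidase that makes hydrogen peroxide, fell from 8.55 ± 0.43 to 5.41 ± 0.065 (log2, SD, n = 6 each). Its PCK level lay below the median of the table, so the size of its fall and its rank are not exact, as for any gene below with a group near the bottom of the range. Car3, a cytosolic carbonic anhydrase, fell, at -2.85 ± 0.46 (adjusted p = 0.000508), with a wide PCK spread of 1.17 (SD).

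**Figure D2:**
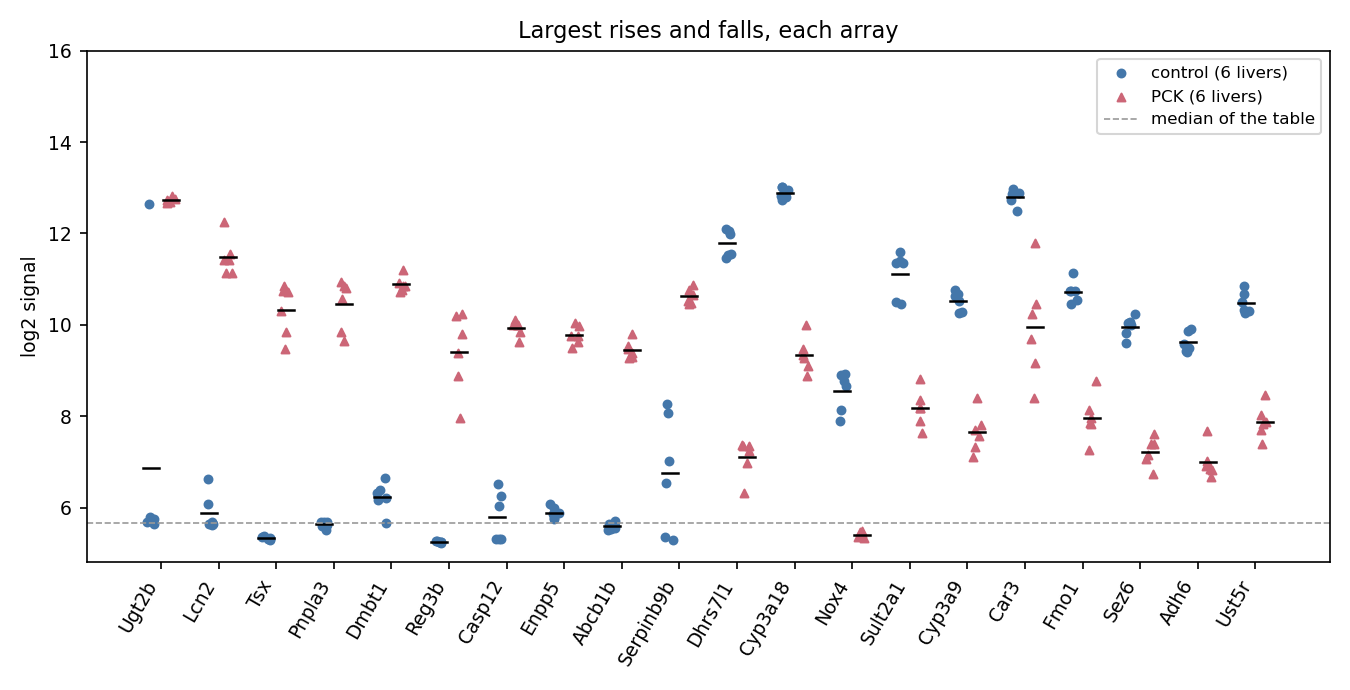
log2 signal (y axis) of the 10 genes with the largest rises and the 10 with the largest falls, 1 point per liver with 6 control (circles) and 6 PCK livers (triangles); bars mark group means and the dashed line the median of the table, 5.66. The groups do not overlap in any of the 20 genes, and for Ugt2b control 4 lies at 12.65 beside the PCK livers.

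Groups of genes were compared through 35 lists fixed before the data were examined, each against all other genes with camera at a preset correlation of 0.01. Camera called 18 lists, 12 higher and 6 lower. With a correlation estimated from the arrays 2 of the 18 calls held, cell cycle and male-biased liver genes, both at an adjusted p of 0.00824. Of 100 divisions of the arrays into 6 and 6, the real one included, 7 gave 18 or more lists. The 6 others had 4 or 5 arrays of 1 group together, and so held part of the group difference. The 46 with 3 arrays of each group on both sides gave a median of 4 lists and at most 11. Camera at the preset correlation thus called lists without a group difference, so its adjusted p may be too small. None of the other divisions drawn called more than 3 genes. Of the 18 list calls 11 held in each of the 23 settings with the preset correlation; the 7 others are given below with the range of their adjusted p.

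**Figure D3:**
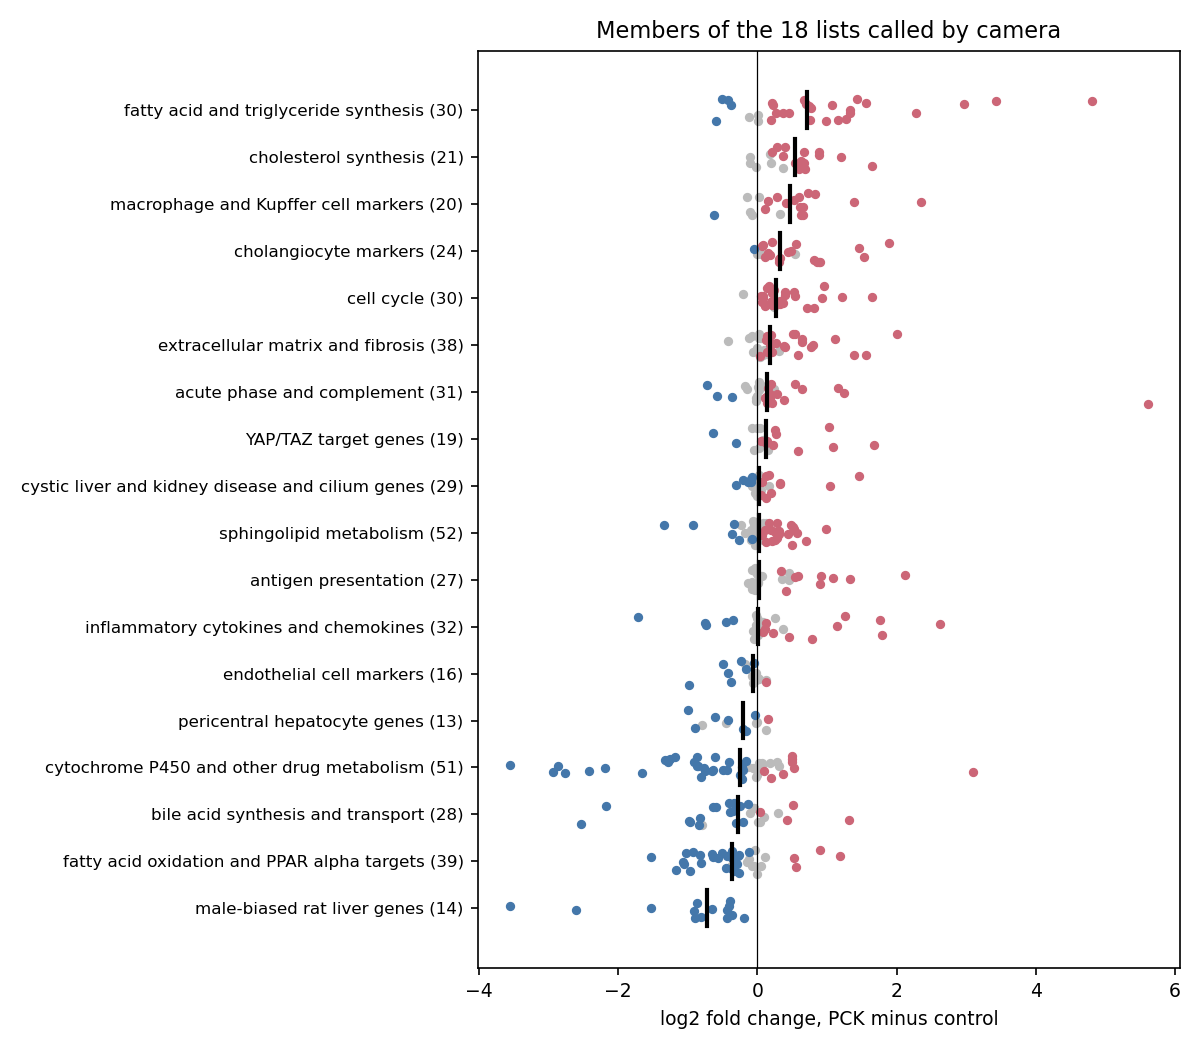
log2 fold change, PCK minus control (x axis), of each measured member of the 18 lists called by camera, with the number of members in brackets. Coloured points passed the limma test over all genes (red higher, blue lower), grey points did not, and black bars are list medians, from -0.73 for male-biased liver genes to 0.72 for fatty acid and triglyceride synthesis.

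Markers of bile duct epithelium rose. Of 24 measured cholangiocyte markers, 19 were higher and 1, Tff3, was lower; the counts were the same adjusted over the list alone (camera adjusted p = 3.44e-10; adjusted p = 0.0893 with an estimated correlation). Krt19, a keratin of bile duct cells, rose from 5.80 ± 0.11 to 7.68 ± 0.32 (log2, SD, n = 6 each; limma adjusted p = 1.67e-06), Tspan8 by 1.54 from a control level near the bottom of the range, 5.25, and Bicc1, an RNA-binding protein whose loss gives cystic kidneys, by 1.46. Epcam rose by 0.90, Krt8 by 0.88 and Krt7 by 0.44. Of 29 cystic disease and cilium genes, 10 were higher and 6 lower, again also adjusted over the list alone (camera adjusted p = 0.0401, 0.0258 to 0.317 over the other settings; adjusted p = 0.302 with an estimated correlation). The list holds Bicc1 and Pkhd1; Pkd2, encoding the ciliary channel polycystin 2, rose by 0.32, and Pkd1, at 0.00065, did not pass the test (adjusted p = 0.990).

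Cell division genes rose together. Of 30 measured members 28 were higher and none lower, in the test over all genes and adjusted over the list alone (camera adjusted p = 9.79e-19, and 0.00824 with an estimated correlation). The median signal of the list, 5.64, lay below the median of the table, so the sizes of many of these rises are not exact. The 12 members above the median of the gene means shifted by 0.605 ± 0.035 (log2, SE). Mki67, a marker of dividing cells, rose by 1.64 ± 0.11 (log2, SE; limma adjusted p = 1.32e-06) from a control level near the bottom of the range, 5.41, the G1 cyclin Ccnd1 by 1.22 and Cdc20, an activator of the anaphase-promoting complex, by 0.95. YAP and TAZ are co-activators that respond to tissue stiffness and cell contact. Of 19 measured genes of their target list 10 were higher and 2 lower, the same adjusted over the list alone (camera adjusted p = 0.00702, 0.00462 to 0.0812 over the other settings, and 0.161 with an estimated correlation). As set, the list also named the factors themselves, Yap1 and Wwtr1, and their partners Tead1 and Tead2, so it is not made of targets alone. Ajuba rose by 1.68, Ccn1 by 1.08 and Ccn2 by 1.03.

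Matrix genes were higher as well. Of 38 extracellular matrix and fibrosis genes 23 were higher and none lower, 25 and none adjusted over the list alone (camera adjusted p = 6.71e-08; adjusted p = 0.302 with an estimated correlation). The proteoglycan Dcn rose by 2.01 ± 0.33 (log2, SE; limma adjusted p = 0.000613), Mgp, an inhibitor of calcification, by 1.56, and the collagen crosslinking enzyme Loxl1 by 1.39. The fibrillar collagen gene Col1a1 rose by 0.38, while Col3a1, at 0.31, did not pass (adjusted p = 0.0588). Of 19 stellate cell and myofibroblast markers 9 were higher and 5 lower, 9 and 6 adjusted over the list alone, and camera did not call the list (adjusted p = 0.204). The pericyte and stellate cell genes Rgs5, Pdgfrb and Cygb rose by 1.42, 0.94 and 0.79, and Hgf (-0.44), Reln (-0.29) and Lrat (-0.24) fell.

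Macrophage genes rose. Of 20 macrophage and Kupffer cell markers 14 were higher and 1, Cd14, was lower, 15 and 1 adjusted over the list alone (camera adjusted p = 9.37e-05; adjusted p = 0.432 with an estimated correlation). Lyz2, the macrophage lysozyme, rose by 2.35 ± 0.18 (log2, SE; limma adjusted p = 3.34e-06), the galectin Lgals3 by 1.39 and the Kupffer cell receptor Clec4f by 0.83. Lymphocyte and neutrophil lists were not called. Of 20 T and NK cell markers 2 were higher and 2 lower, 1 and 2 adjusted over the list alone (camera adjusted p = 0.756). The highest of these was Cd4, which rat macrophages also express, at 0.82, and the chemokine Ccl5 fell (-0.36), as did perforin, Prf1 (-0.10). Of 11 B and plasma cell markers 2 were higher and 3 lower (camera adjusted p = 0.820), and of 14 neutrophil markers 4 were higher and 1 lower (camera adjusted p = 0.353), with the same counts adjusted over the list alone. The changes were small, 0.12 for Cd22, 0.10 for Blnk and -0.10 for Pax5 among B cell genes, and 0.086 for S100a9, 0.076 for Csf3r and 0.034 for Cxcr2 among neutrophil genes. The adjusted p of Csf3r was 0.0344 (0.0108 to 0.0717 over the settings) and that of Cxcr2 0.0445 (0.0137 to 0.0913). The median signals of the T and NK cell, B cell and neutrophil lists, 5.42, 5.61 and 5.36, lay below the median of the table, so these lists say little about the cells.

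Of 31 acute phase and complement genes 17 were higher and 3 lower, the same adjusted over the list alone (camera adjusted p = 2.58e-05; adjusted p = 0.161 with an estimated correlation). Besides Lcn2, Lbp, the lipopolysaccharide binding protein, rose by 1.247 and complement C6 by 1.16. Hamp, encoding the iron hormone hepcidin, fell (-0.72). Cytokine and chemokine genes went both ways: of 32 measured, 11 were higher and 5 lower, 12 and 5 adjusted over the list alone (camera adjusted p = 0.0401, 0.0259 to 0.227 over the other settings; adjusted p = 0.446 with an estimated correlation). The chemokines Cxcl16, Ccl2 and Ccl21 rose by 2.63, 1.79 and 1.76, and the alarmin Il33 fell (-1.71). Tnf and Il6, at 0.021 and 0.0057, did not pass.

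Antigen presentation genes were higher in 9 of 27, none lower, also adjusted over the list alone (camera adjusted p = 0.0189, 0.000430 to 0.150 over the other settings; adjusted p = 0.582 with an estimated correlation). The immunoproteasome subunits led the list: Psmb9 rose by 2.12 ± 0.19 (log2, SE; limma adjusted p = 7.51e-06), Psmb10 by 1.33 and Psmb8 by 1.09, while B2m, at 0.013, did not pass. The interferon response list, with 10 of 27 higher and 3 lower (10 and 4 adjusted over the list alone), was not called (camera adjusted p = 0.0544); Gbp5 rose by 2.78, Ifi47 by 0.87 and Mx2 by 0.78.

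Lipid synthesis genes rose by large amounts. Of 30 measured genes of fatty acid and triglyceride synthesis 23 were higher, 11 of them at least 2-fold, and 4 lower, with the same counts adjusted over the list alone (camera adjusted p = 1.31e-08; adjusted p = 0.0590 with an estimated correlation). Pnpla3, above, led the list. Acacb, the mitochondrial acetyl-CoA carboxylase, rose by 3.42 ± 0.17 (log2, SE; limma adjusted p = 1.43e-07) and the stearoyl-CoA desaturase Scd by 2.97 ± 0.46 (adjusted p = 0.000436), from 10.26 ± 1.199 to 13.23 ± 0.11 (SD, n = 6 each). The elongase Elovl6 rose by 2.28, Acly, which makes cytosolic acetyl-CoA, by 1.56 and Acaca by 1.32; the transcription factor gene Srebf1 rose by 0.37. The triglyceride synthesis enzyme Dgat2 fell (-0.51).

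Cholesterol synthesis genes were higher in 15 of 21 and lower in none, also adjusted over the list alone (camera adjusted p = 1.75e-06; adjusted p = 0.399 with an estimated correlation). Insig1, a sterol sensor and a target of the SREBP factors, rose by 1.64 ± 0.10 (log2, SE; limma adjusted p = 7.04e-07), phosphomevalonate kinase Pmvk by 1.198 and squalene epoxidase Sqle by 0.88. Fatty acid oxidation and PPAR alpha target genes moved the other way, with 26 of 39 lower and 4 higher, 27 and 4 adjusted over the list alone (camera adjusted p = 2.83e-07; adjusted p = 0.130 with an estimated correlation). The fatty acid hydroxylase Cyp4a2 fell (-1.53), the mitochondrial reductase Decr1 (-1.17), and the carnitine transferases Cpt2 (-1.03) and Cpt1a (-0.83). Cd36, which takes up fatty acids, rose by 1.18.

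Sphingolipid genes moved in both directions. Of 52 measured, 20 were higher and 6 lower, 21 and 11 adjusted over the list alone (camera adjusted p = 0.0126, 0.00594 to 0.125 over the other settings; adjusted p = 0.302 with an estimated correlation). Cers6, the ceramide synthase for C16 ceramides, fell, at -1.34 ± 0.067 (log2, SE; limma adjusted p = 1.80e-07). The lysosomal ceramidase Asah1 rose by 0.99, the GM3 synthase St3gal5 by 0.70 and Sptlc2, a subunit of the enzyme that starts sphingolipid synthesis, by 0.53. The GD3 synthase St8sia1 was lower, at -0.92, at an adjusted p of 0.0328, which ranged from 0.0150 to 0.0708 over the settings. Glycerophospholipid genes were split, 14 of 56 higher and 12 lower (15 and 15 adjusted over the list alone), and were not called (camera adjusted p = 0.919); the median, -0.017, and the mean, 0.0052, differed in sign. The phosphatidate phosphatases Lpin1 and Lpin2 rose by 1.15 and 0.71, and the methyltransferase Gnmt fell (-0.49; adjusted p = 0.0363, 0.00598 to 0.190 over the settings).

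**Figure D4:**
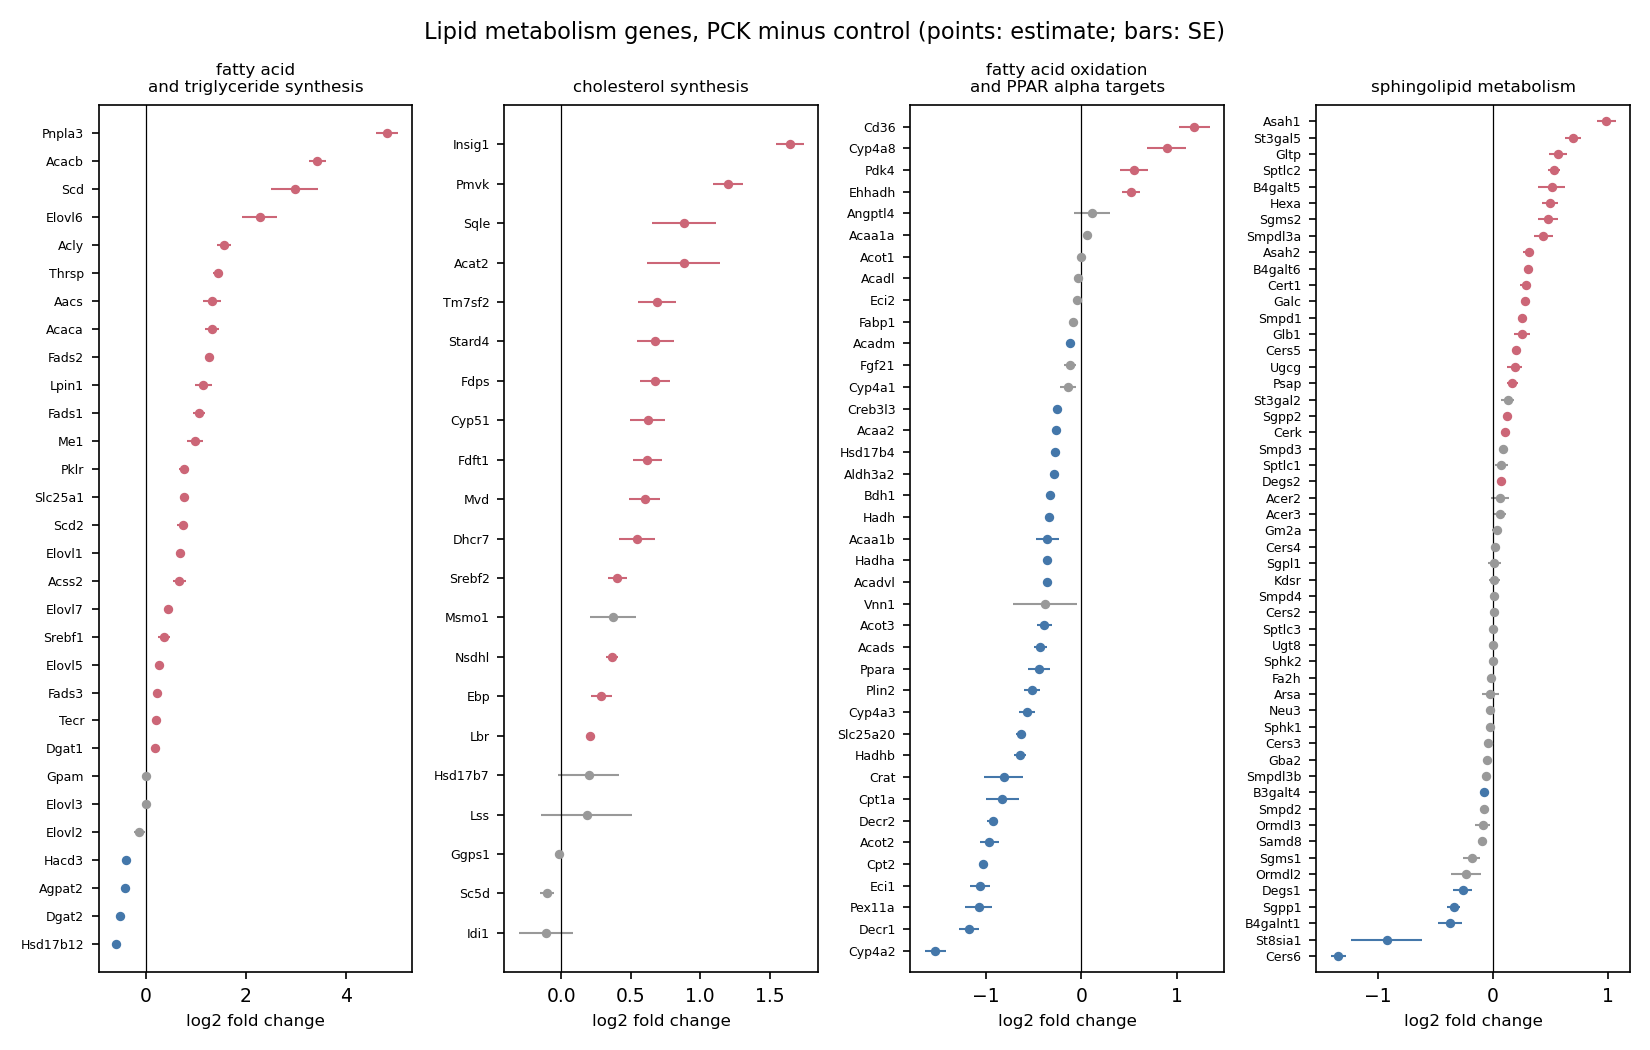
log2 fold change, PCK minus control (x axis), with SE bars from limma, of each measured gene (y axis) in 4 lipid lists, 6 livers per group. Red and blue points passed the test over all genes as higher or lower and grey points did not; fold scales differ between panels, and Pnpla3 at 4.81 and Cers6 at -1.34 are the extremes of their panels.

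Bile acid genes were mostly lower. Of 28 measured, 16 were lower and 4 higher, 18 and 4 adjusted over the list alone (camera adjusted p = 0.000581; adjusted p = 0.0781 with an estimated correlation). Abcg5, part of the canalicular sterol exporter, fell from 7.87 ± 0.57 to 5.34 ± 0.063 (log2, SD, n = 6 each; limma adjusted p = 8.03e-06), a PCK level near the bottom of the range, and the sterol 12-hydroxylase Cyp8b1 (-2.18). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, was at -0.79 and did not pass (adjusted p = 0.0659). Abcc3, a basolateral exporter of bile salts and conjugates, rose by 1.32.

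Of 51 cytochrome P450 and other drug metabolism genes 30 were lower and 8 higher, 31 and 9 adjusted over the list alone (camera adjusted p = 0.000512; adjusted p = 0.198 with an estimated correlation). The glutathione transferase Gstm3 went against the list, with a rise of 3.10 ± 0.43 (log2, SE; limma adjusted p = 0.000197). The 14 measured male-biased liver genes were all lower, also adjusted over the list alone, with a median of -0.73 (camera adjusted p = 3.07e-09; adjusted p = 0.00824 with an estimated correlation). Besides Cyp3a18, Ust5r and Cyp4a2, they included Cyp2c11, the main male-specific P450 of rat liver, which fell (-0.87). Of 15 female-biased genes 3 were higher and 5 lower, also adjusted over the list alone, and the list was not called (camera adjusted p = 0.692). Its median was 0.014 and its mean -0.41, the mean set by Sult2a1, Cyp3a9 and Fmo1.

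Of 20 general hepatocyte markers 3 were higher and 9 lower, also adjusted over the list alone, with a median of -0.042, and the list was not called (camera adjusted p = 0.166). The transcription factor Hnf4a fell (-0.29), Tdo2 (-0.36) and Rgn (-0.42); Alb was the brightest gene on every array, so quantile normalization fixed its value. Other members, Tf, Ahsg, Ttr and Serpina1 among them, lay near the top of the range as well (list median signal 12.78, table maximum 13.98), where changes are compressed, so the small median does not show that hepatocyte genes were stable. The 11 markers no brighter than the brightest male-biased gene shifted by -0.124 (log2, chosen after the result was seen). Of 13 pericentral hepatocyte genes 7 were lower and 1 higher, 8 and 1 adjusted over the list alone (camera adjusted p = 0.0358, 0.00740 to 0.0779 over the other settings; adjusted p = 0.432 with an estimated correlation). Tbx3 fell from 6.77 ± 0.28 to 5.77 ± 0.051 (log2, SD, n = 6 each), and so did the glutamate transporter Slc1a2 (-0.90) and Cyp1a2 (-0.61). Of 16 periportal genes 2 were higher and 6 lower, 3 and 8 adjusted over the list alone, and the list was not called (camera adjusted p = 0.410; median -0.057, mean 0.043). Aldh1b1, an aldehyde dehydrogenase, rose by 2.57 and histidase, Hal, and serine dehydratase, Sds, fell (-1.14 and -0.80; for Sds adjusted p = 0.0226, 0.00967 to 0.140 over the settings).

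Endothelial markers, unlike those of bile duct and macrophages, were lower, 7 of 16 with 1 higher, also adjusted over the list alone (camera adjusted p = 0.0271, 0.00497 to 0.0725 over the other settings; adjusted p = 0.424 with an estimated correlation). The sinusoidal lectin Clec4g fell (-0.99), Ehd3 (-0.49) and the VEGF receptor Flt1 (-0.43). Lists of genes of blood and neighbouring organs were not called. Of 10 red blood cell genes 1, Tmcc2, was lower, at -0.50, and none higher, also adjusted over the list alone (camera adjusted p = 0.823; median -0.0063, mean 0.015). Of 21 pancreas, fat and muscle genes 2 were higher and 6 lower, also adjusted over the list alone (camera adjusted p = 0.258), with Adipoq, the fat cell hormone adiponectin, higher by 0.40, Des by 0.12 and Cidec lower, at -0.28. Adipoq was at a PCK mean of 5.72, and the adjusted p was 0.0330 for Des (0.0143 to 0.0800 over the settings) and 0.0381 for Cidec (0.00376 to 0.132).

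The remaining lists were not called. Of 28 glucose metabolism genes 7 were higher and 8 lower, 9 and 8 adjusted over the list alone (camera adjusted p = 0.724); the insulin receptor substrate Irs1 fell, at -1.59 ± 0.093 (log2, SE; limma adjusted p = 5.18e-07), Ugp2 fell (-0.81) and liver pyruvate kinase, Pklr, rose by 0.77. Of 18 clock genes 3 were higher and 7 lower, also adjusted over the list alone (camera adjusted p = 0.359): Per2 fell (-1.72) and Cry1 (-0.79), Npas2 rose by 0.74, and Bmal1, at -0.017, did not pass. Of 22 immediate early genes 8 were higher and 3 lower, also adjusted over the list alone (camera adjusted p = 0.103), with Klf6, Egr1 and Jun up by 1.92, 1.81 and 1.22. Of 23 genes of the unfolded protein response 2 were higher and 4 lower, 1 and 3 adjusted over the list alone (camera adjusted p = 0.471), among them Dnajb9 at -0.50 (adjusted p = 0.0329, 0.0156 to 0.0945 over the settings), Edem1 at -0.48 and Sel1l at -0.47. Of 23 NRF2 target and oxidative stress genes 10 were higher and 6 lower, 11 and 6 adjusted over the list alone (camera adjusted p = 0.167); Gclc and Gclm, the subunits of the enzyme that limits glutathione synthesis, fell (-0.67 and -0.67), and malic enzyme, Me1, rose by 0.98. Of 41 oxidative phosphorylation genes 6 were higher and 9 lower, also adjusted over the list alone (camera adjusted p = 0.820), with Cox7c at 0.38, Ndufa1 at -0.31 and Ndufs1 at -0.24.

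The labels give PCK and control rats different strain names, so called genes were also counted by chromosome with the GRCr8 gene table, which placed 16427 genes. The share of genes called differed from the other chromosomes on 7 chromosomes (Fisher's exact test, 2-sided, adjusted p under 0.05): it was above them on chromosomes 2, 5, 7 and 9 and below them on 1, 3 and 4. Shares ran only from 32.0% on chromosome 3 to 44.8% on chromosome 5, and no chromosome differed when genes under the median signal were left out. The labels give no scan date, hybridisation batch or hour of sampling, so a batch or a time of day that followed the groups cannot be told apart from them.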

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

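The tests of cell share, sampling state and within-group levels below, and the grouping of the splits by their make-up, were chosen after the results were seen; the other splits of the arrays and the test of neighbouring genes were set before. A value was singled out where its gap to the nearest of its group exceeded 0.625 of the group's range. Chance does this in about 1 of 20 groups, so about 11.5 of the 230 groups tested (115 items, named genes and component scores, in each of the 2 groups), and 23 were found.

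PCK 6 held the extreme PCK value in 11 of them, values that correlated genes share: Lcn2 at 12.26, Krt19 at 8.28, Mgp at 9.49, Loxl1 at 8.27, Lyz2 at 11.68, Lgals3 at 8.19, Cxcl16 at 10.40, Ccl2 at 9.60, Prf1 at 5.62 and Cxcr2 at 5.38 lay above the other PCK livers and Dhrs7l1 at 6.31 below them. PCK 3 stood apart in Adh6 at 7.68 and Ndufa1 at 6.86, PCK 4 in Rgn at 11.71 and PCK 5 in Cox7c at 12.20. Among control livers, control 5 stood apart in Pkhd1 at 6.60, Loxl1 at 6.26 and Tmcc2 at 6.70, control 4 in Ugt2b at 12.65 and Tspan8 at 5.30, control 3 in Mki67 at 5.50 and Sel1l at 10.55, and control 1 in Ccn1 at 7.98. No component score stood apart by this measure.

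Other divisions of the 12 arrays into 6 and 6 were fitted, 100 of 462 drawn with the real one included. Only the real one called 6362 genes, and the highest other count was 3, so chance is excluded for the number of genes (1 of 100). The same held for genes changed at least 2-fold, with 261 in the real division and at most 1 in another (1 of 100). For the number of lists this count does not exclude chance: 7 of 100 divisions called 18 or more, and the highest other count was 22. All 6 others had 4 or 5 arrays of 1 group together and so shared part of the real difference. The 46 divisions with 3 arrays of each group on both sides called a median of 4 lists and at most 11. Lists were thus also called without a group difference, and the count does not show that the lists fail to separate the groups either.

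The first pattern was the rise of bile duct and macrophage markers beside the fall of hepatocyte metabolism genes, for which a lower share of hepatocytes in cystic tissue, raising the markers of every other cell type alike, may be a candidate explanation. Over members above the median signal, the endothelial markers shifted by -0.227 ± 0.041 (log2, SE, 12 members), against 0.771 ± 0.083 for cholangiocytes (14) and 0.504 ± 0.100 for macrophages (18). Dilution alone would have raised them all. The endothelial fall was known when this test was chosen, and marker levels within endothelial cells may also differ. The test therefore does not decide on dilution as a cause of the rises. Stellate cell and myofibroblast markers rose by 0.267 (95% interval 0.175 to 0.359, 13 members), as dilution would also give, so a part for it beside more or activated cells of those types remains open. Dilution would also lower hepatocyte genes alike, yet 11 hepatocyte markers no brighter than the brightest male-biased gene shifted by -0.124 ± 0.017, against -1.002 ± 0.042 for male-biased genes and -0.620 ± 0.052 for drug metabolism genes. These markers were matched only by an upper limit of signal, so compression may still differ between the sets. A loss of hepatocyte share therefore stays open, and the marker shift does not limit its size. The disease itself stays open as well, and batch and strain cannot be told apart from disease here.

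The second pattern was the rise of fatty acid synthesis genes with the fall of oxidation genes, which might reflect a more fed state or another time of day at sampling. Genes that fasting raises (Pck1, G6pc1, Igfbp1, Irs2, Ppargc1a and Tat) shifted by 0.231 ± 0.143 (log2, SE; 95% interval -0.088 to 0.551; exact permutation p = 0.147), so a fed state was neither shown nor excluded. Of these genes only Irs2 passed the gene test, and it was lower, at -0.22 (limma adjusted p = 0.00426). Igfbp1 at 0.81 and G6pc1 at 0.77 had the largest rises and did not pass. No signal limit was set here, and Ppargc1a lay below the median of the table in both groups. A clock phase score over members above the median signal, Bmal1 and Npas2 minus Per1, Per2, Dbp, Tef and Usp2, differed by 0.881 ± 0.165 (log2, SE, exact permutation p = 0.00216, the smallest possible). The changes of Npas2 and Per2 were known when the score was chosen, so its p is no independent support for another time of day. The score rested on Npas2, Per2, Usp2 and Tef, while Bmal1 at -0.017, Dbp at -0.052 and Per1 at 0.095 did not pass the gene test. Nor did Nr1d1 at 0.070, Per3 at -0.026 and Ciart at 0.014, members left out of the score for their low signal. The clock genes did not move together, so the score does not decide. The labels give food without limit for all rats and no hour of sampling, so time of day stays open beside disease and strain.

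The third pattern was genes near the floor in 1 group and clearly expressed in the other: of 67 genes changed at least 4-fold, 12 had 1 group's mean below the table's median, 9 higher and 3 lower in PCK, among them Tsx, Reg3b, Abcb1b, Pnpla3 and Nox4. Sequence variants that differ between or within the strains could give such values through a lost gene or lost probe binding. Among control livers 5 genes (Ugt2b, Cyp2d5, Acy3, RT1-N2 and Lyc2) showed 2 separate levels, with a gap of at least 1.5 log2 covering at least 0.75 of the range, and among PCK livers 0. In Ugt2b, Cyp2d5, Acy3 and Lyc2 just 1 liver stood apart, control 5 in both Cyp2d5 and Lyc2. More genes varied widely in control livers, with an SD of at least 0.5 in 96 genes against 37 in PCK livers. The median SD over all genes was close, 0.045 in control and 0.041 in PCK livers. Variants still segregating in the control strain would give such separate levels, and so could single outlying livers. Of the 5 genes only Ugt2b is among the largest changes. Serpinb9b and Casp12, also among the largest rises, varied between control livers without meeting this rule, from 5.30 to 8.26 and from 5.31 to 6.51. PCK livers in turn varied in Car3, with an SD of 1.17, and in Reg3b, with an SD of 0.87. Neighbouring pairs of 2-fold genes with unlike names numbered 6, in 5 of which both genes changed in the same direction. The median was 4 such pairs in 10000 shuffles among genes above the median signal (shuffle permutation p = 0.296), which decides nothing. With like-named pairs kept there were 13 against a median of 5 (permutation p = 5.0e-04), as gene families changing together also give. Among the largest changes, Casp12, Enpp5 and Serpinb9b lay beside like-named genes (Casp4, Enpp4 and Serpinb9). Cyp3a9 and Sez6 lay beside unlike-named ones (Gjc3 and Pipox). Without genotypes, variant and disease cannot be told apart for these or the other changed genes.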

How the results depend on the processing

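The centring on bright genes and the setting without 3 arrays were chosen after the data were seen; the other settings were planned. The count of changed genes, 6362, stayed within 1.5 times in every setting run, from 4273 at adjusted p under 0.01 to 7056 with every probe set tested, of which 736 unnamed probe sets were called when they were included; 6242 were called without moderation and 4608 with genes under the median signal left out, where fewer genes were tested. Quantile normalization over named genes alone called 6501, while equal medians and averaging of probe sets moved nothing, since the deposited columns already share 1 distribution and each gene has 1 probe set. The replicate number does not pair the rats: deviations of same-numbered livers correlated from -0.137 to 0.165 (median -0.012), and 2 of 12 arrays correlated best with their own number. With it as a block 5423 genes were called, 5230 of them among the 6362, with 261 at least 2-fold and 16 lists. With control 5, control 6 and PCK 6 left out together the counts were 5570 genes, 258 at least 2-fold and 14 lists, and Pkhd1 was at 0.80. Leaving out each array in turn gave 5731 to 6367 genes, 250 to 269 genes at least 2-fold, 15 to 19 lists and 0.92 to 1.14 for Pkhd1, which was called in each of these settings.

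Centring on the brightest 25% of genes moved the median of all genes from -0.0067 to 0.016 and raised the called genes to 6904 (4361 higher, 2543 lower, against 2882 and 3480); 5425 of the 6362 genes were among them, 261 genes changed at least 2-fold (175 higher, 86 lower, against 168 and 93, so not all the same genes), and 13 lists were called. The direction of small changes therefore depends on the centring. Testing against a 1.2-fold change with limma's treat gave 949 genes against 261 at least 2-fold, as a lower bound on the fold admits more genes. Camera with an estimated correlation called 2 lists against 18, and fry, which does not compare with other genes, 27; under fry the glycerophospholipid list turned lower (adjusted p = 0.0394) where camera gave it as higher and not called; the cause was not tested. Scaling each gene to unit variance lowered the share of the first component from 74.5% to 36.1%, as dim genes then weigh as much as bright ones. The 7 chromosomes became 0 with genes under the median signal left out; the cause was not tested. Of 111 named genes 103 were called in every setting that tested them. The filters on signal left out some dim genes: Blnk was tested in 21 of 23 settings, and Adipoq, Pkd2, Prf1 and S100a9 in 22. Cidec, Csf3r, Cxcr2, Des, Dnajb9, Gnmt, Sds and St8sia1 lost the call in some settings, and no named gene reversed. Signal limits the calls: 3.13% of the dimmest eighth of genes and 61.2% of the brightest eighth were called. That 0 genes under the median mean signal were called at 2-fold is nearly fixed by the scale. Such a gene would need 1 group close to the minimum of the values.

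Adjusted p of lists whose call changed, by setting: genes under the median signal left out (pericentral 0.0779, endothelial 0.0725, cystic disease 0.317, YAP/TAZ 0.0812, cytokines 0.227), genes under the lower quartile of signal left out (pericentral 0.0687, endothelial 0.0545, cystic disease 0.0732, cytokines 0.0788, interferon response 0.0453), every probe set tested (interferon response 0.0406), eBayes with trend and robust (interferon response 0.0480), replicate block (cystic disease 0.0516, cytokines 0.0519), arrays centred on the brightest 25% of genes (cystic disease 0.189, YAP/TAZ 0.0787, sphingolipid 0.125, cytokines 0.150, antigen presentation 0.150), 3 arrays left out together (pericentral 0.0617, endothelial 0.0559, cystic disease 0.0617, cytokines 0.0504), camera with an estimated correlation (cholangiocyte 0.0893, pericentral 0.432, matrix 0.302, macrophage 0.432, endothelial 0.424, cystic disease 0.302, YAP/TAZ 0.161, sphingolipid 0.302, fatty acid synthesis 0.0590, fatty acid oxidation 0.130, cholesterol synthesis 0.399, bile acids 0.0781, drug 0.198, acute phase and complement 0.161, cytokines 0.446, antigen presentation 0.582), fry (hepatocyte 0.000535, periportal 0.0407, stellate cell and myofibroblast 0.0122, pancreas with fat and muscle 0.0418, glycerophospholipid 0.0394, female-biased 0.0139, interferon response 0.0337, circadian clock 0.00384, immediate early genes 0.00362). Leaving out each array in turn gave adjusted p of 0.0258 to 0.0743 for cystic disease, 0.0112 to 0.0540 for endothelial, 0.0259 to 0.0604 for cytokines, 0.0221 to 0.135 for interferon response, 0.0137 to 0.0600 for pericentral.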

Other observations

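The genes of this part were chosen after their values were seen, and their families were not among the lists tested. They were not tested as groups. Of 21 genes of heat shock proteins and co-chaperones looked at, 16 were lower in PCK livers, 2 were higher and 3 did not pass in the limma test over all genes. Hsph1, a nucleotide exchange factor of Hsp70, fell, at -1.89 ± 0.12 (log2, SE; adjusted p = 9.28e-07), Chordc1 (-1.34), Stip1, which joins Hsp70 and Hsp90, (-1.28), Ahsa2 (-1.21) and Cacybp (-0.94). The abundant Hsp90ab1 fell (-0.40). The lens and muscle small heat shock protein Cryab went the other way, at 2.60 ± 0.18 (adjusted p = 1.55e-06), with Hspa4l at 0.74. Dnajb1, at -0.42 (adjusted p = 0.0502), Hspa4 and Hspd1 did not pass.

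Some genes of the calcium-binding annexin and S100 families were higher. Of 12 annexins 7 were higher, none was lower and 5 did not pass, and the largest rise was that of Anxa2, a membrane-binding protein of epithelia, which rose from 6.79 ± 0.45 to 9.77 ± 0.31 (log2, SD, n = 6 each; limma adjusted p = 1.80e-06), followed by Anxa5 at 1.62 and Anxa3 at 1.19. Of 16 S100 genes 8 were higher, none was lower and 8 did not pass, with S100a11 at 2.61 ± 0.25 (SE; adjusted p = 1.29e-05) and the annexin 2 partner S100a10 at 0.39. The constitutive androstane receptor Nr1i3, a nuclear receptor of drug response, fell, at -2.42 ± 0.20 (adjusted p = 4.55e-06). Of 8 genes looked at, the receptor with targets of it, 6 fell and none rose, among them Cyp2b2 at -2.19, Cyp2b1 at -1.26, Por at -1.33 and Aox1 at -2.19; Cyp2b1 and Cyp2b2 are near-identical and were not told apart further here.

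The control livers alone separated in a few genes. RT1-N2, a class I gene of the rat major histocompatibility complex, was at 7.66 in control 2 and 7.65 in control 6 and at 5.50 to 5.51 in the other control livers. Cyp2d5 was at 8.14 in control 5 and at 5.57 to 5.85 in the others, Acy3 at 7.99 in control 3 and at 9.84 to 10.15 in the others, and Lyc2 at 5.64 in control 5 and at 9.81 to 10.22 in the others. The mean difference between PCK and control livers did not pass the test in any of these 4 genes, whose control livers varied widely. In Lyc2 the PCK livers, at 10.65 to 10.98, still lay above all control livers. PCK livers lay just below all control livers in Cyp2d5, at 5.44 to 5.51, and in RT1-N2, at 5.41 to 5.48, both near the bottom of the range. In Acy3 they were at 8.75 to 9.01, between control 3 and the other control livers.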
